A study of Homo sapiens with 8 samples.

How the data were processed

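The count table deposited by the authors holds reads per gene, as whole numbers, for 23368 gene symbols and 8 libraries. A further table deposited by the authors holds RPKM for the same genes and libraries. Per the submitters' processing notes, TopHat2 2.0.13, featureCounts and edgeR 3.14.0 were used with the hg19 build, without a stated order or annotation version. Columns were matched to the labels by name (D for dox, T24 for TPA), which is a reading of short names that the labels do not spell out. In each library the deposited RPKM equalled the counts over gene length and TMM-scaled library size, with a largest spread of the factor of 2.37e-09 over 7441 genes, so both tables hold the same measurement. Counts were used for all main results and RPKM for alternatives. The reads were not realigned, and the notes do not say how reads shared by several genes were handled.

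Genes were kept by filterByExpr with the 4 groups, which left 14469, and 3872 genes had no read. Among the symbols 28 had been turned into dates by a spreadsheet and were kept as they stood but not named. Libraries were scaled by TMM factors, and edgeR QL with robust dispersions was fitted with a coefficient per group. Comparisons were dox against untreated, dox+TPA against TPA, TPA against untreated, dox+TPA against dox, dox+TPA against untreated, and the interaction (the dox effect with TPA minus that without). Adjusted p values are Benjamini-Hochberg over all tested genes of a comparison, and a gene passed under 0.05. Standard errors are the log2 fold change over the square root of its F statistic. The fit was tested on simulated data made from these counts: a 2-fold change was found in 97.0% of cases for dox without TPA and in 91.0% for dox with TPA, and a 1.5-fold change in 68.7% and 62.7%. Of the genes called, 5.35% and 7.14% were unchanged. Only genes with at least 1 CPM untreated were changed, all groups varied alike, and no other gene responded. The rates hold for that setting and may differ in the real data.

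The labels do not state that replicates came from separate cultures, so p values measure only the spread between these samples, which may be technical. The series holds no dox-treated line without the transgene, so effects of dox and of MKL1 are not separated. Intervals and floors given for genes near silence cover counting error only. Leaving out a library leaves a group with a single library, which is then assumed to vary like the other groups.

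The comparisons, the tests, 24 gene lists from general knowledge and the rule for naming genes were chosen before the data were examined. The lists hold 577 genes, of which 564 were found, and 23 lists were tested; the list of mitochondrially encoded genes had 0 members in the table. Lists were tested by camera on log2-CPM (prior count 2) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation and by fry. The SRF-MRTF and YAP-TEAD lists share 4 genes, and 8 other pairs share 1. The rule named, per comparison, the 8 largest rises and 8 largest falls that passed, had a mean of at least 5 CPM in a compared group and no overlap between groups (not asked of the interaction). Symbols starting with LOC, LINC, MIR or SNOR, or with an antisense or intronic transcript ending, were passed over. Other pseudogenes and uncharacterised genes were kept. It added up to 2 rises and 2 falls per list and 20 genes fixed in advance; some were left out for length, and some are not reported here.

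Alternatives were DESeq2 (1.42.0), RLE, upper-quartile and library-size scaling, no filter, a filter of 1 CPM in 2 libraries, a replicate block, fits of just the compared groups, a fold of at least 2, an adjusted p under 0.01, RPKM with limma at pseudocounts 1 and 0.1, and each library left out. A crossed replicate block and the removal of gene length and GC content trends were added after the data had been seen. Length was known for 100% and GC content for 94.6% of tested genes. R 4.3.3, edgeR 4.0.16, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used. Genomic positions are not given, since the annotation at hand is of another build than the deposited tables.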

Results

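Poly(A) RNA was sequenced in 8 libraries from HEL-iMKL1, a human erythroleukaemia line (HEL) that carries a doxycycline-inducible MKL1 gene. MKL1, also called MRTFA, is a coactivator of serum response factor (SRF), the transcription factor behind many actin and smooth-muscle-type cytoskeletal genes. The cells fell into 4 groups of 2 libraries: untreated, doxycycline (dox, 10 ng/ml), the phorbol ester TPA (15 nM), and both together, each treatment lasting 24 hours. TPA activates protein kinase C and drives lines of this kind towards megakaryocytes, the cells that shed platelets. The libraries held 36417758 and 39385857 counted reads (untreated), 42796318 and 37304885 (dox), 37602106 and 43414545 (TPA), and 12238348 and 44891499 (dox+TPA), so dox+TPA replicate 1 was the shallowest. Expression is given as CPM (counts scaled to a common depth, with TMM factors), and 1 CPM stood for 11.88 reads in that library and for 34.56 to 44.66 reads in the others. EEF1A1 was the most abundant gene in each library, with 1.915% to 2.267% of the reads.

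Replicates of a group correlated at r = 0.9888 to 0.9964 across genes, and libraries of different groups at 0.9209 to 0.9932, genes not being independent replicates. The first principal component (77.1% of variance) parted the libraries with TPA from those without. The second (12.7%) placed the dox libraries below their partners without dox in both states. Among well expressed genes the SD of the log2 difference between replicates was 0.166 (untreated), 0.127 (dox), 0.203 (TPA) and 0.277 (dox+TPA).

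**Figure D1:**
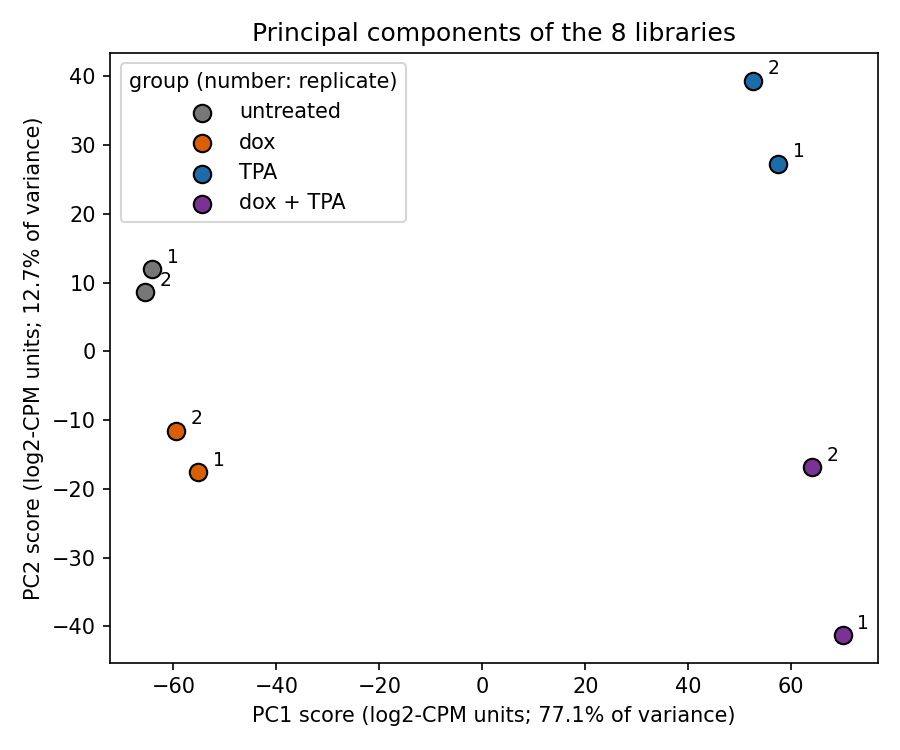
Scores of the 8 libraries on the first 2 principal components of log2-CPM over 14469 genes; each point is a library, coloured by group and numbered by replicate. Libraries with TPA lie at 52.66 to 69.99 on the first component and those without at -65.46 to -55.2.

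MKL1 itself was measured first, since the labels name it as the induced gene, and reads from the transgene and from the resident gene count alike. MKL1 RNA stood at 187.5 and 185.5 CPM in the untreated libraries and at 1571 and 1236 CPM with dox, a 7.53-fold rise (log2 fold change 2.91 ± 0.14 SE, n = 2 per group, edgeR QL adjusted p = 2.67e-08). With TPA alone it stood at 458.6 and 366.6 CPM, 2.21-fold above untreated (1.15 ± 0.13, edgeR QL adjusted p = 5.18e-06). With dox and TPA it reached 4710 and 4796 CPM, 11.5-fold above TPA alone (3.53 ± 0.14, edgeR QL adjusted p = 3.6e-09) and 25.5-fold above untreated. The dox effect on MKL1 with TPA exceeded that without by 0.61 ± 0.18 on the log2 scale, a difference that did not pass (edgeR QL adjusted p = 0.0863).

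SRF RNA, the partner of MKL1, differed little with dox alone (0.23 ± 0.13, edgeR QL adjusted p = 0.562). It was 1.34-fold higher with dox in TPA-treated cells (0.42 ± 0.13, edgeR QL adjusted p = 0.0333), a call lost without TPA replicate 2 (adjusted p = 0.282) or dox+TPA replicate 1 (0.139). With TPA alone SRF was 1.27-fold higher (edgeR QL adjusted p = 0.0404), a call lost without untreated replicate 1 (0.455), TPA replicate 1 (0.307), dox replicate 1 (0.0843) or dox replicate 2 (0.083). The paralog MKL2 (MRTFB) fell 2.62-fold with TPA (-1.39 ± 0.12, edgeR QL adjusted p = 3.63e-07) and did not pass with dox (-0.30, adjusted p = 0.35). MYOCD, the muscle member of the family, had 0 reads in all 8 libraries, which allows up to 0.252 CPM in dox+TPA replicate 1 at a floor of 3 reads per library.

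The comparison of dox with no treatment addresses what MKL1 induction does in cells without TPA. Among the largest rises with dox were 2 actin genes near silence in untreated cells: ACTG2 and ACTA2, the enteric and vascular smooth muscle actins, rose 241-fold (7.91 ± 0.17, from 0.721 ± 0.119 to 175 ± 6.06 CPM, mean ± SD, n = 2) and 151-fold (7.24 ± 0.20, from 0.198 ± 0.0645 to 30.6 ± 0.996 CPM). KRT17, an intermediate filament keratin, rose 125-fold (6.97 ± 0.33), and RPE65, the retinoid isomerase of the visual cycle, 76.5-fold (6.26 ± 0.26). KRT17 and RPE65 were near silence in untreated cells too, with 12 and 8 reads over the group, so the size of their folds rests on few reads. GLIPR1 rose 16.8-fold, SIRPB2, a signal-regulatory protein, 15.2-fold, and the interferon-inducible GTPase GBP2 11.2-fold (3.49 ± 0.11, from 8.16 ± 0.422 to 91.7 ± 3.26 CPM). The falls were small: TTC39B fell 1.96-fold (-0.97 ± 0.12, from 27.5 ± 1.2 to 14.0 ± 0.179 CPM), WNT5A, a secreted signalling ligand, 1.82-fold (-0.86 ± 0.13), and the collagen receptor subunit ITGA2 1.66-fold (-0.73 ± 0.14). Actins and keratins have close paralogs and pseudogenes, and how reads shared between them were counted is not stated.

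Of 14469 genes tested, 146 passed with dox alone (1.01%), 125 higher and 21 lower, and 78 of these changed at least 2-fold, 77 higher and 1 lower. The 8 largest rises under the rule for naming genes, MKL1 included, had edgeR QL adjusted p values from 5.84e-12 to 3.33e-07 and kept their calls with each of the 8 libraries left out in turn. Of the 8 largest falls, TTC39B (edgeR QL adjusted p = 0.000761) did so too, and WNT5A (0.0027) lost its call without untreated replicate 2 (0.0568). SLC16A7 (-1.01), CCDC144B (-0.96), FGF23 (-0.85), ZBTB37 (-0.77), ITGA2 and CD226 (-0.67) had edgeR QL adjusted p values from 0.00676 to 0.0383, and each lost its call without dox replicate 1 (adjusted p from 0.132 to 0.656) and without untreated replicate 1 (0.123 to 0.444). Leaving out untreated replicate 2 took it from 6 of the 8 falls (0.0568 to 0.305) and leaving out dox replicate 2 from 3 (0.0554 to 0.0915). The count itself was 57 without untreated replicate 1, 68 without untreated replicate 2 and 77 without dox replicate 1, and 399 (210 higher, 189 lower) and 391 (229, 162) without dox+TPA replicate 1 or 2, although the latter are not in the comparison. The share of rises depended on the fit. The calls split 142 higher and 72 lower with DESeq2, 231 and 145 with no filter, 301 and 226 with a GC content trend removed, 441 and 460 with just the 2 groups compared, and 446 and 483 with a crossed replicate block.

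Among gene lists, the cytoskeletal targets of SRF and MRTF moved up with dox: of 38 tested, 11 were higher, 0 lower and 27 not past, with 27 higher when adjusted over the list alone. Their median log2 fold change was 0.44 (camera adjusted p = 8.18e-22), although with an estimated correlation among the genes the camera adjusted p = 0.207. MYL9, the smooth muscle myosin light chain, was too sparse to test, with 0 reads untreated and 10 with dox, at least 3.21-fold higher against a floor of 3 reads over the group. MYH9, the non-muscle myosin heavy chain of platelets, and VCL (vinculin) did not pass, at 0.44 ± 0.13 and 0.32 ± 0.10 (edgeR QL adjusted p = 0.211 and 0.197). Of 15 immediate early genes driven by SRF with its TCF partners, EGR3 was higher and 14 did not pass, with 3 higher adjusted over the list alone (median 0.09, camera adjusted p = 0.0503). That list passed without untreated replicate 1 (camera adjusted p = 0.0166) or dox replicate 2 (0.00291), and with a replicate block (0.025), RLE factors (0.0392) or the filter of 1 CPM (0.041). EGR3 (1.78 ± 0.34, edgeR QL adjusted p = 0.0209) lost its call without dox replicate 1 (0.135), untreated replicate 1 (0.333) or untreated replicate 2 (0.124).

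Megakaryocyte genes were largely not past with dox alone. Of 38 effector genes of megakaryocytes and platelets, GP5, a subunit of the von Willebrand factor receptor, was 1.64-fold higher (0.71 ± 0.14), ITGA2 and CD226 were lower, and 35 did not pass, with 2 higher and 5 lower adjusted over the list alone. The GP5 call (edgeR QL adjusted p = 0.0222) was lost without dox replicate 1 (0.109), dox replicate 2 (0.0915), untreated replicate 1 (0.478) or untreated replicate 2 (0.15). The platelet integrin ITGA2B stood at 0.02 ± 0.12 and its partner ITGB3 at -0.34 ± 0.11 (edgeR QL adjusted p = 0.974 and 0.26). The effector list had a median of -0.06 (camera adjusted p = 0.0768, and 0.00801 without untreated replicate 1 or 0.00418 with a GC content trend removed). Of the 21 megakaryocyte and erythroid transcription factors 0 passed by edgeR QL over all genes or over the list alone, and 3 had an unadjusted p under 0.05 (median -0.08, camera adjusted p = 0.0768, and 0.03 without untreated replicate 1, 0.0397 without dox replicate 1 or 0.00265 with the GC content trend removed). Of 32 erythroid genes, FECH, the last enzyme of haem synthesis, was higher (0.51, edgeR QL adjusted p = 0.0403) and 31 did not pass (camera adjusted p = 0.878). The FECH call was lost without either dox library (adjusted p = 0.483 and 0.255), either untreated library (0.574 and 0.193) or either TPA library (0.0545 and 0.0554).

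Of the 9 lists that passed by camera with dox alone, just that of SRF and MRTF targets passed by fry (fry adjusted p = 0.00354), and the other 8 are described here. By edgeR QL 0 members passed over all genes for the mitotic, ribosomal protein, cholesterol, histone, AP-1 and NF-kB, monocyte and DNA replication lists, with 9, 7, 7, 3, 2, 3 and 2 members at an unadjusted p under 0.05. All 25 mitotic genes had negative values (median -0.24, camera adjusted p = 3.26e-07, and 0.4 with an estimated correlation). All 46 cytosolic ribosomal protein genes had positive values (median 0.18, camera adjusted p = 4.05e-07, and 0.453 with an estimated correlation). The median became 0.04 when a gene length trend was removed (camera adjusted p = 0.0665). With that trend removed the histone, AP-1 and NF-kB, and monocyte lists lost their calls too (camera adjusted p = 0.181, 0.0784 and 0.0531), as the monocyte list did with a GC content trend removed (0.188). With the filter of 1 CPM the histone, monocyte and DNA replication lists lost theirs (camera adjusted p = 0.0955, 0.0955 and 0.0513). Cholesterol synthesis (22 genes, median -0.17, 1 lower adjusted over the list alone, and 0 in the 6 other lists named here) had camera adjusted p = 0.00103, 0.4 with an estimated correlation, and 0.328 without untreated replicate 2. Markers of other lineages (15 genes, median 0.24) had KRT8 higher and 4 higher adjusted over the list alone, with camera adjusted p = 0.00908, and 0.343 with an estimated correlation. KRT8 lost its call without dox replicate 1 (edgeR QL adjusted p = 0.347), untreated replicate 1 (0.41) or untreated replicate 2 (0.266). Histones (18 genes, median 0.40) had camera adjusted p = 0.014, 0.627 with an estimated correlation, and 0.501 without untreated replicate 2. The response genes of AP-1 and NF-kB (26 genes, median 0.20, or 0.16 with 4 near-silent genes set to their bounds) had camera adjusted p = 0.026, 0.359 with an estimated correlation, and 0.151 without untreated replicate 2. Monocyte and granulocyte markers (12 genes, median 0.26) had camera adjusted p = 0.0296, 0.359 with an estimated correlation, 0.125 without untreated replicate 1 and 0.0925 without dox replicate 1. DNA replication genes (25, median -0.06) had camera adjusted p = 0.0317 and 0.453 with an estimated correlation. That call was lost without untreated replicate 2 (0.501), dox replicate 1 (0.134) or dox+TPA replicate 2 (0.0532). The remaining 10 lists had camera adjusted p from 0.0809 to 0.83; among them the interferon list (median -0.03, mean 0.10, test up) and the hypoxia list (median 0.09, mean -0.01, test up) differed in sign between measures. Polyploidization and ERK feedback genes passed without untreated replicate 1 (camera adjusted p = 0.015 and 0.0473) and heat shock genes without dox replicate 2 (0.047). With a GC content trend removed the polyploidization, ERK feedback and ATF4 lists passed (camera adjusted p = 0.00593, 0.045 and 0.0067).

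**Figure D2:**
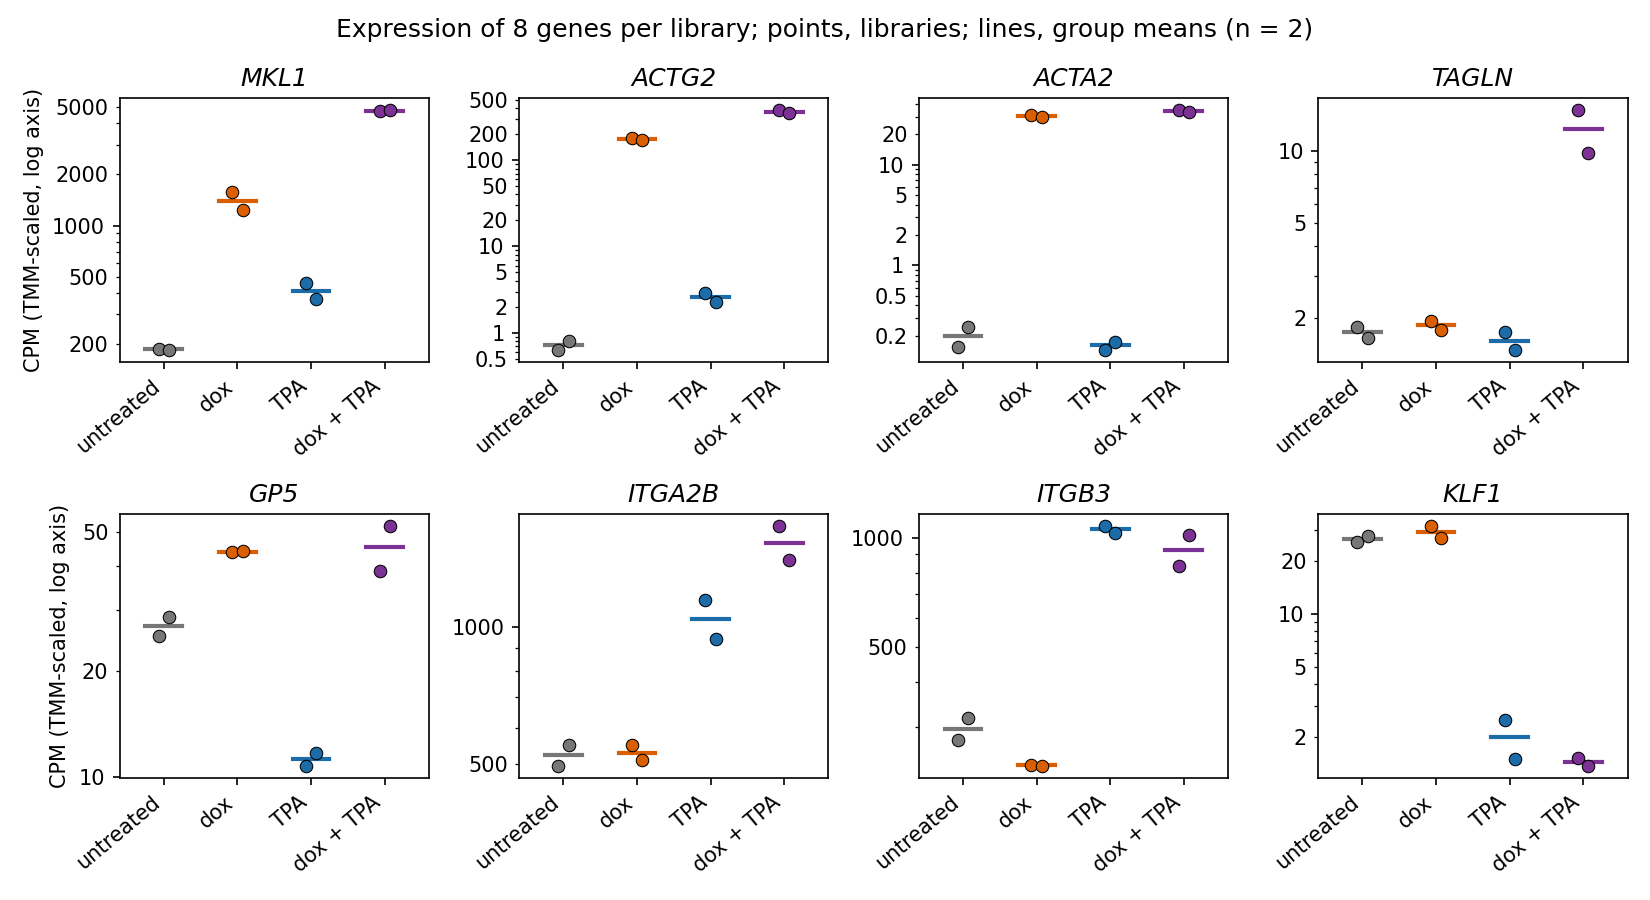
CPM (TMM-scaled, log axis) of 8 genes in the 4 groups; points are libraries and lines group means (n = 2). ACTG2 goes from a mean of 0.721 CPM untreated to 175 with dox. GP5 goes from 26.9 untreated to 44 with dox, and from 11.2 with TPA to 45.4 with dox+TPA.

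In TPA-treated cells, the same 2 actin genes were among the largest rises with dox. ACTA2 rose 209-fold (7.71 ± 0.21, from 0.159 ± 0.0207 to 34.2 ± 1.08 CPM, n = 2), ACTG2 141-fold (7.14 ± 0.15) and KRT17 84.5-fold (6.40 ± 0.24). RPE65 rose 103-fold, from just 7 reads over the TPA group, FAM71F1 92.2-fold, ITGB1BP3 27.1-fold and C1orf95 15-fold. S100A2 and S100A6, calcium-binding proteins, fell 6.56-fold (-2.71 ± 0.15) and 2.77-fold (-1.47 ± 0.11). HSPA5, the main chaperone of the endoplasmic reticulum, fell 3.24-fold (-1.70 ± 0.11), and HERPUD1, which acts in the removal of misfolded proteins there, 2.86-fold (-1.52 ± 0.13).

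The other large falls were GFPT2 (-1.98), PRR9 (-1.81), the secreted glycoprotein STC1 (-1.63) and myoglobin, MB (-1.56). All 16 of these largest rises and falls, MKL1 included, had edgeR QL adjusted p values from 5.19e-12 to 0.000135 and kept their calls in each of the 8 omissions. In all, 3329 of 14469 genes passed (23.0%), 1650 higher and 1679 lower, with a median size of 0.57 on the log2 scale and 622 changed at least 2-fold, 545 higher and 77 lower. The count was 1025 without TPA replicate 2. The split depended on the fit, with 2193 higher and 856 lower under upper-quartile factors, 2055 and 779 under library size alone, 1720 and 1160 with the filter of 1 CPM, 2176 and 1153 with a gene length trend removed, and 955 and 449 with just the 2 groups compared. Lower genes were the more numerous with DESeq2 (1352 higher and 1626 lower), with a replicate block in which the untreated replicate numbers were exchanged (2674 and 3349) and without dox+TPA replicate 2 (1950 and 2579).

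Of the 38 SRF and MRTF cytoskeletal targets, 21 were higher with dox in TPA-treated cells, 1 lower (ANXA1) and 16 not past, with 23 and 1 adjusted over the list alone. The median was 0.49 (camera adjusted p = 1.97e-10, and 0.237 with an estimated correlation). MYH9 was 1.43-fold higher (0.51 ± 0.13, edgeR QL adjusted p = 0.017), a call lost without TPA replicate 2 (0.2) or dox+TPA replicate 1 (0.0872). MYL9 had 0 reads with TPA and 21 with dox+TPA, at least 9.26-fold higher against a floor of 3 reads over the group. The ANXA1 call (edgeR QL adjusted p = 0.045) was lost in 7 of the 8 omissions, all but that of dox+TPA replicate 1, with adjusted p up to 0.258. Of the 15 immediate early genes of SRF and TCF, 6 were higher, among them NR4A1 (1.24 ± 0.15) and EGR4 (1.33 ± 0.18), the phosphatase DUSP5 was lower (-0.61 ± 0.12), and 8 did not pass. Adjusted over the list alone, 7 were higher and 1 lower (median 0.13, camera adjusted p = 0.196).

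Platelet genes went both ways with dox under TPA. GP5 was 4.08-fold higher (2.03 ± 0.15, from 11.2 ± 0.687 to 45.4 ± 9.44 CPM, edgeR QL adjusted p = 1.23e-06), and ITGA2B 1.47-fold higher (0.55 ± 0.12, edgeR QL adjusted p = 0.00577, and 0.0937 without TPA replicate 2). GP5 stood at 26.9 ± 2.33 CPM untreated and 44 ± 0.11 with dox alone, so its level with both treatments was close to that with dox alone. The platelet chemokine PPBP was 2.41-fold lower (-1.27 ± 0.13, edgeR QL adjusted p = 2.9e-05). Of the 38 effector genes 9 were higher, 7 lower and 22 not past, with 12 and 8 adjusted over the list alone (median 0.08, camera adjusted p = 0.337). PF4, the other platelet chemokine, had 4 to 9 reads per group and was not tested. Of the 21 transcription factors 1 was higher, 2 lower and 18 not past (0 and 1 adjusted over the list alone, camera adjusted p = 0.428). The higher one, ZFPM1, and the lower ones, TAL1 and ETS1, each lost the call without TPA replicate 2 (edgeR QL adjusted p = 0.292, 0.135 and 0.214). ZFPM1 also lost it without either dox+TPA library (0.221 and 0.0906) or either untreated library (0.0639 and 0.0657), TAL1 without either dox library (0.0641 and 0.0642), and ETS1 in all others but that of dox+TPA replicate 2 (0.0815 to 0.235). GATA1, FLI1, RUNX1 and NFE2 did not pass (edgeR QL adjusted p = 0.391, 0.622, 0.0746 and 0.675). Of the 32 erythroid genes 4 were higher, among them the erythropoietin receptor EPOR (1.02 ± 0.16), 8 were lower, among them the beta globin HBB (-0.72 ± 0.15), and 20 did not pass. Adjusted over the list alone 6 were higher and 10 lower (camera adjusted p = 0.931).

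Ribosome biogenesis genes and MYC were lower together with dox under TPA. Of 22 tested, 0 were higher, 16 lower and 6 not past (0 and 19 adjusted over the list alone, median -0.56), among them MYC (-0.84 ± 0.12) and ODC1, the first enzyme of polyamine synthesis (-0.87 ± 0.10). Of 12 heat shock and chaperone genes 10 were lower, among them HSPA8 (-0.92 ± 0.11) and HSPH1 (-0.95 ± 0.12), HSPB1 was higher and 1 did not pass, with the same counts adjusted over the list alone (median -0.55). The HSPB1 call (edgeR QL adjusted p = 0.0119) was lost without TPA replicate 2 (0.117), dox+TPA replicate 1 (0.228), dox replicate 1 (0.0588) or dox replicate 2 (0.0622). Of 25 mitotic genes 0 were higher, 9 lower, such as CCNB1 (-0.57 ± 0.10), and 16 not past (0 and 10 adjusted over the list alone, median -0.35). Of 23 interferon response genes 5 were higher, such as ISG15 (1.36 ± 0.23), 1 was lower and 17 did not pass (6 and 1 adjusted over the list alone, median 0.37). Of 23 genes of the ATF4 stress response 8 were lower, such as DDIT3 (-0.97 ± 0.11) and the cystine carrier SLC7A11 (-1.32 ± 0.20), 1 was higher and 14 did not pass (11 and 1 adjusted over the list alone, median -0.26). Camera adjusted p values for these 5 lists were 1.91e-08, 9.92e-05, 9.92e-05, 0.00149 and 0.031. With an estimated correlation the camera adjusted p values were 0.177, 0.251, 0.409, 0.19 and 0.395. The ATF4 call was lost without TPA replicate 1 (camera adjusted p = 0.154) or dox+TPA replicate 2 (0.154).

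Further lists did not pass by camera with dox under TPA, although single members did, and 6 of them passed by fry. These were ERK feedback, YAP-TEAD, AP-1 and NF-kB, hypoxia, other lineages and monocytes (fry adjusted p = 0.00293, 0.00514, 0.0058, 0.021, 0.0223 and 0.025). Of 26 AP-1 and NF-kB response genes 9 were lower, such as the chemokine CCL2 (-1.34 ± 0.12), 1 was higher (JUND) and 16 did not pass, with 11 and 3 adjusted over the list alone (camera adjusted p = 0.148, and 0.0221 without dox+TPA replicate 1 or 0.0134 with a GC content trend removed). JUND (0.57 ± 0.12, edgeR QL adjusted p = 0.0057, and 0.0677 without TPA replicate 2) turned to -0.10 when a GC content trend was removed. Of 46 ribosomal protein genes 2 were lower, RPL14 and RPS23, and 44 did not pass, with 0 past adjusted over the list alone. That list had a median of -0.13 (camera adjusted p = 0.148, and 0.0366 without TPA replicate 2 or 2.21e-05 without dox+TPA replicate 1). Of 26 integrin and focal adhesion genes 8 were higher, such as TNS1 (0.88 ± 0.11), 5 lower, such as ITGA6 (-0.98 ± 0.14), and 13 did not pass (9 and 5 adjusted over the list alone, camera adjusted p = 0.206). The other 10 lists had camera adjusted p from 0.148 to 0.931. Among them the median and the test differed in sign for the YAP-TEAD targets (median -0.09, mean 0.33), the p53 targets (-0.02, 0.04) and the list of polyploidization and G1 regulators (-0.05, 0.02). The mean alone differed for DNA replication genes (0.01, median -0.08) and histones (-0.07, median 0.14). Of 66 list members named by the rule for this comparison, 36 lost their call in at least 1 omission.

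Whether dox acted differently with and without TPA was tested as an interaction. TAGLN (transgelin), a smooth muscle marker, stood at 1.73 ± 0.14 CPM untreated, 1.86 ± 0.106 with dox, 1.60 ± 0.191 with TPA and 12.4 ± 3.6 with both (n = 2), an interaction of 2.80 ± 0.32 on the log2 scale. Positive interactions also appeared for the chromatin remodeller CHD5 (2.08 ± 0.19), the small GTPase RHOB (2.03 ± 0.24), C1orf95 (2.84 ± 0.28) and the collagen COL25A1 (1.64 ± 0.21). COL25A1 changed direction, from 15.2 CPM untreated to 9.95 with dox, and from 2.63 with TPA to 5.17 with both. C1orf95 stood at 4.18 CPM untreated, 8.76 with dox, 0.395 with TPA and 6.08 with both. S100A2 and S100A6 went the other way (-3.03 ± 0.22 and -1.63 ± 0.16): TPA alone raised S100A2 from 2.98 ± 0.474 to 39.7 ± 1.79 CPM, and with dox+TPA it stood at 6.18 ± 0.664 CPM. INSIG1, a brake on cholesterol synthesis, had 1.10 ± 0.14 (edgeR QL adjusted p = 0.00321).

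The 5 rises and the pair of S100 genes had edgeR QL adjusted p values from 3.27e-05 to 0.00313 and, like INSIG1, kept their calls in all 8 omissions. The other large positive interactions were WWC1 (2.19), CALD1 (1.64) and DUSP5P (1.59), a pseudogene, each lost without untreated replicate 2 (edgeR QL adjusted p from 0.0629 to 0.149). WWC1 and DUSP5P were also lost without TPA replicate 2 (0.0921 and 0.0552), and WWC1 without untreated replicate 1 (0.121), dox replicate 1 (0.0626) or dox replicate 2 (0.098). The other large negative interactions were GFPT2 (-4.14), FASLG (-2.14), GLIPR1 (-1.90), PRR9 (-1.63) and STC1 (-1.61). GLIPR1 rose with dox in both states, from 0.397 to 6.74 CPM without TPA and from 7.15 to 32.1 CPM with it. The GLIPR1 interaction turned to 0.40 from RPKM with pseudocount 1, filtered or not, and kept its sign at pseudocount 0.1. GFPT2 had 3 reads in the untreated group, so that its value depends on the prior count. These 5 lost the edgeR QL call without untreated replicate 1 in 4 cases (adjusted p from 0.0543 to 0.132), untreated replicate 2 in 4 (0.0749 to 0.151), TPA replicate 2 in 4 (0.0557 to 0.0871), dox replicate 1 in 3 (0.0683 to 0.0856), dox replicate 2 in 2 (0.0744 to 0.105) and dox+TPA replicate 2 in 1 (0.0638).

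In all 290 genes passed for the interaction (2.0%), 145 higher and 145 lower, of which 90 and 35 reached 2-fold, and a simulated interaction of 1.5-fold was found in 23.9% of cases against 91.0% for 2-fold. The count was 37 without untreated replicate 1, 16 without untreated replicate 2, 78 without dox replicate 1, 72 without dox replicate 2 and 23 without TPA replicate 2. It was 738 and 895 without dox+TPA replicate 1 or 2. The split was 176 higher and 101 lower with RLE factors, 229 and 89 with upper-quartile factors, and 227 and 54 with library size alone, which shifted the median of all genes by 0.12. It was 672 and 293 with no filter, 168 and 79 with the filter of 1 CPM, 330 and 206 with a replicate block, and 229 and 96 with a gene length trend removed. Lower genes were the more numerous with the exchanged replicate block (1044 higher and 1456 lower) and without dox+TPA replicate 1 (363 and 375) or 2 (413 and 482), and the split was 258 and 260 with DESeq2.

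Among ribosome biogenesis genes and MYC, the dox effect was lower with TPA for part of the list: of 22, 0 were higher, 8 lower and 14 not past (0 and 19 adjusted over the list alone, median -0.54, camera adjusted p = 2.57e-09, and 0.139 with an estimated correlation). Heat shock and chaperone genes had 5 of 12 lower, 0 higher and 7 not past (7 and 1 adjusted over the list alone, median -0.45, camera adjusted p = 0.000249, and 0.277 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 46 past by edgeR QL, with 21 at an unadjusted p under 0.05 (0 higher and 3 lower adjusted over the list alone, median -0.32, camera adjusted p = 1.9e-05, 0.591 with an estimated correlation, and 0.0787 without dox+TPA replicate 2). AP-1 and NF-kB response genes had 3 of 26 lower, 0 higher and 23 not past (8 and 1 adjusted over the list alone, median -0.31, camera adjusted p = 0.00161, 0.165 with an estimated correlation, and 0.0755 without dox+TPA replicate 2). Interferon response genes had 1 of 23 higher and 22 not past (2 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 0.00415, and 0.165 with an estimated correlation). Cholesterol synthesis had 2 of 22 higher, LSS (1.15 ± 0.18) and INSIG1, and 20 not past (5 higher and 1 lower adjusted over the list alone, median 0.24, camera adjusted p = 0.00431, 0.486 with an estimated correlation, and 0.0621 without untreated replicate 2). LSS lost its call without TPA replicate 2 (edgeR QL adjusted p = 0.0655) or untreated replicate 2 (0.0882).

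For megakaryocyte and platelet effectors the interaction had a median of 0.25 (camera adjusted p = 0.0148, and 0.486 with an estimated correlation; fry adjusted p = 0.105), and the members past went both ways: GP5 was higher (1.32 ± 0.20), PPBP (-1.19 ± 0.17) and CD63 (-0.65 ± 0.13) were lower, and 35 of 38 did not pass. Adjusted over the list alone 7 were higher and 3 lower. GP5 stood at 26.9 CPM untreated, 44 with dox, 11.2 with TPA and 45.4 with both, so it was similar with dox in both states and lowest with TPA alone. The list lost its call without untreated replicate 2 (camera adjusted p = 0.0836) or dox+TPA replicate 2 (0.0787), and GP5 without untreated replicate 2 (edgeR QL adjusted p = 0.0749). PPBP lost its call without untreated replicate 1 (edgeR QL adjusted p = 0.0693) or 2 (0.0744), and CD63 without either untreated library, either dox library or TPA replicate 2 (0.101 to 0.184). The interaction of ITGA2B, 0.54 ± 0.17, did not pass (edgeR QL adjusted p = 0.103). By camera with the preset correlation 7 of 23 lists passed for the interaction, by fry 7, and with an estimated correlation 0. By fry the ribosomal protein and cholesterol lists did not pass either (fry adjusted p = 0.167 and 0.0798), while the ATF4, YAP-TEAD and hypoxia lists did (0.0412, 0.0395 and 0.0395).

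SRF and MRTF cytoskeletal targets differed little as a list: TAGLN and CALD1 were higher, ANXA1 lower and 35 of 38 not past (2 and 1 adjusted over the list alone). ANXA1 lost its call without either untreated library, either dox library or TPA replicate 2 (edgeR QL adjusted p from 0.0783 to 0.139). Their median was -0.05, their mean 0.17 and the test up (camera adjusted p = 0.324). The other 15 lists had camera adjusted p from 0.0564 to 0.993, with signs differing between measures for the immediate early genes (median 0.005, mean -0.06, test up), the erythroid genes (median 0.07, mean 0.04, test down) and the markers of other lineages (median -0.10, mean 0.004, test down). The ATF4 list passed without untreated replicate 2, TPA replicate 2 or dox+TPA replicate 1 (camera adjusted p = 0.0288, 0.0157 and 0.0209), and with a GC content trend removed (0.017) or the filter of 1 CPM (0.0467). Histones passed without untreated replicate 1, TPA replicate 2 or dox+TPA replicate 1 (camera adjusted p = 0.0105, 0.0227 and 0.00131), and the transcription factors without untreated replicate 1 (0.0475), with library size alone (0.0374) or with the filter of 1 CPM (0.0467). DNA replication genes passed with the GC content trend removed (camera adjusted p = 0.0373).

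**Figure D3:**
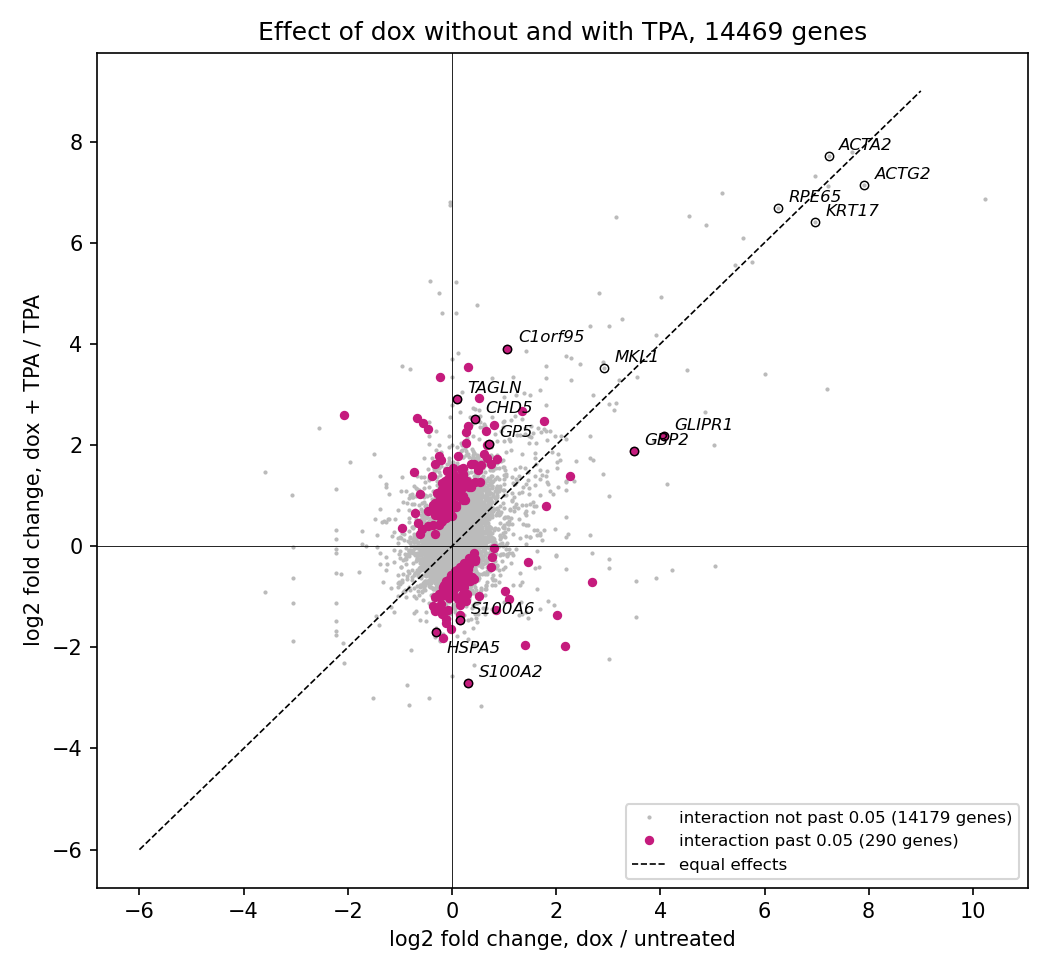
Log2 fold change of each of 14469 genes with dox in untreated cells (x axis) and in TPA-treated cells (y axis); coloured points are the 290 genes past 0.05 for the interaction and the dashed line marks equal effects. ACTG2, ACTA2, KRT17 and RPE65 lie near the line, and TAGLN, CHD5 and S100A2 far from it.

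The genes that dox moved in the absence of TPA were compared with those it moved in its presence, contrasts that share no library. Of the 125 genes higher without TPA, 104 were also higher with TPA, against 14.3 for independent sets, and of the 21 lower 8 were also lower, against 2.44. Just 2 passed in opposite directions, and 138 of the 146 had the same sign in both states. The median size among the 125 was 1.47 without TPA and 1.36 with it, and 55 of them had the larger effect with TPA. The 125 were chosen by passing without TPA, which tends to raise their values in that state. These values therefore do not show in which state dox acted more strongly. Across all genes the fold changes correlated at r = 0.465. The 112 shared genes became 53 without untreated replicate 1, 59 without untreated replicate 2, 71 without dox replicate 1, 172 without dox+TPA replicate 1 and 249 without dox+TPA replicate 2.

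Among the largest changes with TPA alone were rises of genes weakly expressed or silent in untreated cells. GZMB, the protease granzyme B, rose 1470-fold (10.52 ± 0.16, from 0.994 ± 0.217 to 1470 ± 37 CPM, n = 2), and IL2RA, the interleukin-2 receptor alpha chain, 667-fold (9.38 ± 0.23). INHBA, an activin subunit, had 0 reads untreated and was at least 506-fold higher, and TMEM158 at least 137-fold. CCL3, a chemokine, SERPINB2, a protease inhibitor, TM7SF4 and CORO2B had 1 to 3 reads untreated, with ratios of 5210 (95% counting interval 1440 to 43000), 1510 (516 to 7320), 1360 (464 to 6590) and 3050 (547 to 120000). KLF1, the erythroid master regulator, fell 13.5-fold (-3.76 ± 0.19, from 26.7 ± 1.47 to 1.99 ± 0.705 CPM).

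The other large falls with TPA were the receptor kinase EPHB4 (21.3-fold), MYO5B (13.9-fold), CPEB1 (13.8-fold), STEAP3, an iron reductase of erythroid cells (12.7-fold), the antiviral gene RSAD2 (12.6-fold) and ST6GALNAC5 (10.1-fold). These 15 genes had edgeR QL adjusted p values from 5.53e-14 to 3.26e-08 and kept their calls in each omission. In all 7533 genes passed (52.1%), 3965 higher and 3568 lower, and 2847 changed at least 2-fold, 1792 higher and 1055 lower. Scaling by library size alone moved the median of all genes by -0.20 on the log2 scale and the split to 2893 higher and 5235 lower, so directions here are relative to the TMM scale.

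Of the 38 megakaryocyte and platelet effectors 21 were higher with TPA, 5 lower and 12 not past (22 and 7 adjusted over the list alone, median 0.67). ITGA2B rose 1.99-fold (0.99 ± 0.12), ITGB3 3.55-fold (1.83 ± 0.11), ITGA2 13.9-fold (3.80 ± 0.15) and the tetraspanin CD9 5.85-fold (2.55 ± 0.11), with edgeR QL adjusted p from 1.92e-10 to 1.03e-05. F13A1, the clotting factor XIII subunit (-3.14 ± 0.41), and SERPINE2, a protease inhibitor (-2.22 ± 0.64), were lower, the latter on 4 reads with TPA and not past without TPA replicate 1 (edgeR QL adjusted p = 0.0751). GP1BA did not pass (0.15 ± 0.12, edgeR QL adjusted p = 0.322). Of the 21 transcription factors 7 were higher, such as ETS1 (2.28 ± 0.11), ERG (1.62 ± 0.11) and FLI1 (0.65 ± 0.09), 5 were lower, such as KLF1, BCL11A (-1.77 ± 0.13) and NFE2 (-0.92 ± 0.10), and 9 did not pass (7 and 6 adjusted over the list alone). GATA1 stood at -0.29 ± 0.12 (edgeR QL adjusted p = 0.054) and RUNX1 at -0.02 ± 0.10 (0.894). Of the 32 erythroid genes 23 were lower, such as KLF1, 6 were higher and 3 did not pass, with the same counts adjusted over the list alone (median -1.25). The higher ones included the fetal globin HBG2 (1.15 ± 0.12), with its close paralog HBG1 (1.003 ± 0.106), and the embryonic globin HBE1 (1.79 ± 0.29).

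Mitotic and DNA replication genes fell with TPA, and immediate early and ERK feedback genes rose. All 25 mitotic genes were lower (median -1.41), such as KIF20A (-1.94 ± 0.11), and 24 of 25 DNA replication genes were (median -1.18), with 1 not past and the same counts adjusted over the list alone. Of 22 ribosome biogenesis genes with MYC 21 were lower and 1 not past (22 adjusted over the list alone, median -0.64). The cell cycle inhibitor CDKN1A rose 5.23-fold (2.39 ± 0.10), and MYH10, the non-muscle myosin that is switched off as megakaryocytes become polyploid, fell 6.59-fold (-2.72 ± 0.10). All 15 immediate early genes of SRF and TCF were higher (median 3.45), such as EGR3, 318-fold (8.31 ± 0.21), and all 26 AP-1 and NF-kB response genes (median 3.20), also adjusted over each list alone. Of 13 ERK feedback genes 12 were higher, such as DUSP6 (3.91 ± 0.10), and 1 did not pass, also over the list alone (median 2.46). Of 26 integrin and focal adhesion genes 21 were higher, such as ITGA6 (6.12 ± 0.18), and 5 did not pass (23 higher adjusted over the list alone, median 1.24).

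Of the 38 SRF and MRTF cytoskeletal targets 24 were higher with TPA, such as CYR61 (3.02 ± 0.12) and the fibronectin receptor subunit ITGA5 (2.03 ± 0.09), 2 were lower, TPM1 (-0.95 ± 0.09) and CALD1 (-0.93 ± 0.19), and 12 did not pass, also adjusted over the list alone. The median was 0.74, or 0.71 with 3 near-silent genes at their bounds. MYH9 rose 2.04-fold (1.03 ± 0.14) and VCL 2.39-fold (1.25 ± 0.10). Of 16 YAP-TEAD targets 11 were higher, 1 was lower and 4 did not pass (11 and 2 adjusted over the list alone, median 0.94, or 0.77 with 2 genes at their bounds). Of 19 hypoxia and glycolysis genes 14 were higher, such as NDRG1 (3.66 ± 0.11), 2 lower and 3 not past, also over the list alone (median 0.75). Of 15 markers of other lineages 9 were higher, such as PDGFRA (3.55 ± 0.19), 1 lower and 5 not past, also over the list alone (median 1.09). Of 12 monocyte and granulocyte markers 5 were higher, such as TLR4 (2.93 ± 0.17) and ITGAX (3.05 ± 0.24), 2 lower, SPI1 (-0.71 ± 0.19) and CEBPA (-1.77 ± 0.28), and 5 not past, also over the list alone (median 0.41). The SPI1 call was lost without TPA replicate 2 (edgeR QL adjusted p = 0.0679) or untreated replicate 2 (0.0539). Of 23 ATF4 genes 12 were higher, such as DDIT4 (2.97 ± 0.12), 5 lower and 6 not past (13 and 6 adjusted over the list alone). Of 16 p53 targets 9 were higher, such as BTG2 (2.82 ± 0.12), 2 lower and 5 not past (9 and 3 adjusted over the list alone).

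By camera 16 of the 23 lists passed with TPA. The adjusted p was 1.25e-13 for AP-1 and NF-kB, 1.59e-12 for mitotic, 3.83e-11 for DNA replication, 7.07e-11 for immediate early, 2.93e-08 for integrin and 3.35e-08 for ERK feedback genes (camera). It was 4.68e-07 for ribosome biogenesis, 4.02e-06 for erythroid, 7.1e-05 for SRF and MRTF, 0.000345 for hypoxia, 0.000564 for YAP-TEAD and 0.00131 for megakaryocyte effector genes (camera). It was 0.0165 for other lineages, 0.0253 for monocytes, 0.0356 for ATF4 and 0.0395 for p53 (camera), and the last 3 were lost without TPA replicate 1 (adjusted p = 0.0528, 0.0515 and 0.0569) or with a GC content trend removed (0.067, 0.0633 and 0.0633). With an estimated correlation just AP-1 and NF-kB (camera adjusted p = 0.0319) and ERK feedback (0.0422) passed. The other 14 then had camera adjusted p values of 0.0522 for immediate early genes, 0.0673 for hypoxia and for ribosome biogenesis, 0.074 for DNA replication, and 0.104 for mitotic, erythroid, integrin, YAP-TEAD and other-lineage genes. They were 0.137 for monocyte and p53, 0.144 for megakaryocyte, 0.178 for SRF and MRTF and 0.256 for ATF4 genes (camera adjusted p).

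The 7 lists that did not pass by camera with TPA moved in parts, and by fry all but ribosomal proteins and histones passed. The fry adjusted p was 0.000915 for polyploidization, 0.0146 for cholesterol, 0.0361 for heat shock and 0.0444 for the transcription factors. Ribosomal proteins had 10 of 46 higher, 0 lower and 36 not past (0 adjusted over the list alone, median 0.18, camera adjusted p = 0.0697). That list passed without untreated replicate 2, dox+TPA replicate 1 or dox+TPA replicate 2 (camera adjusted p = 0.0308, 0.0382 and 0.035). Cholesterol synthesis had 10 of 22 higher, such as SQLE (1.10 ± 0.11), 3 lower, such as LSS (-2.47 ± 0.13), and 9 not past (12 and 3 adjusted over the list alone, camera adjusted p = 0.0697, and 0.0276 without untreated replicate 2). Heat shock genes had 1 of 12 higher, 5 lower and 6 not past (3 and 5 adjusted over the list alone, camera adjusted p = 0.21). The list of polyploidization and G1 regulators had 6 of 12 higher, such as CCND1 (2.44 ± 0.12), 5 lower, such as CCNE1 (-1.18 ± 0.15), and 1 not past (6 and 6 adjusted over the list alone, camera adjusted p = 0.746). The transcription factors had a median of 0.05, a mean of -0.04 and camera adjusted p = 0.746. Interferon response genes had 8 of 23 higher, such as IFI6 (2.22 ± 0.13), 7 lower, such as RSAD2 and CMPK2 (-3.12 ± 0.12), and 8 not past, also over the list alone. Their median was 0.33 and their mean -0.02, with camera adjusted p = 0.746 upwards and fry adjusted p = 0.0395 downwards. Histones had 3 of 18 higher, 1 lower and 14 not past (3 and 0 adjusted over the list alone, camera adjusted p = 0.949).

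**Figure D4:**
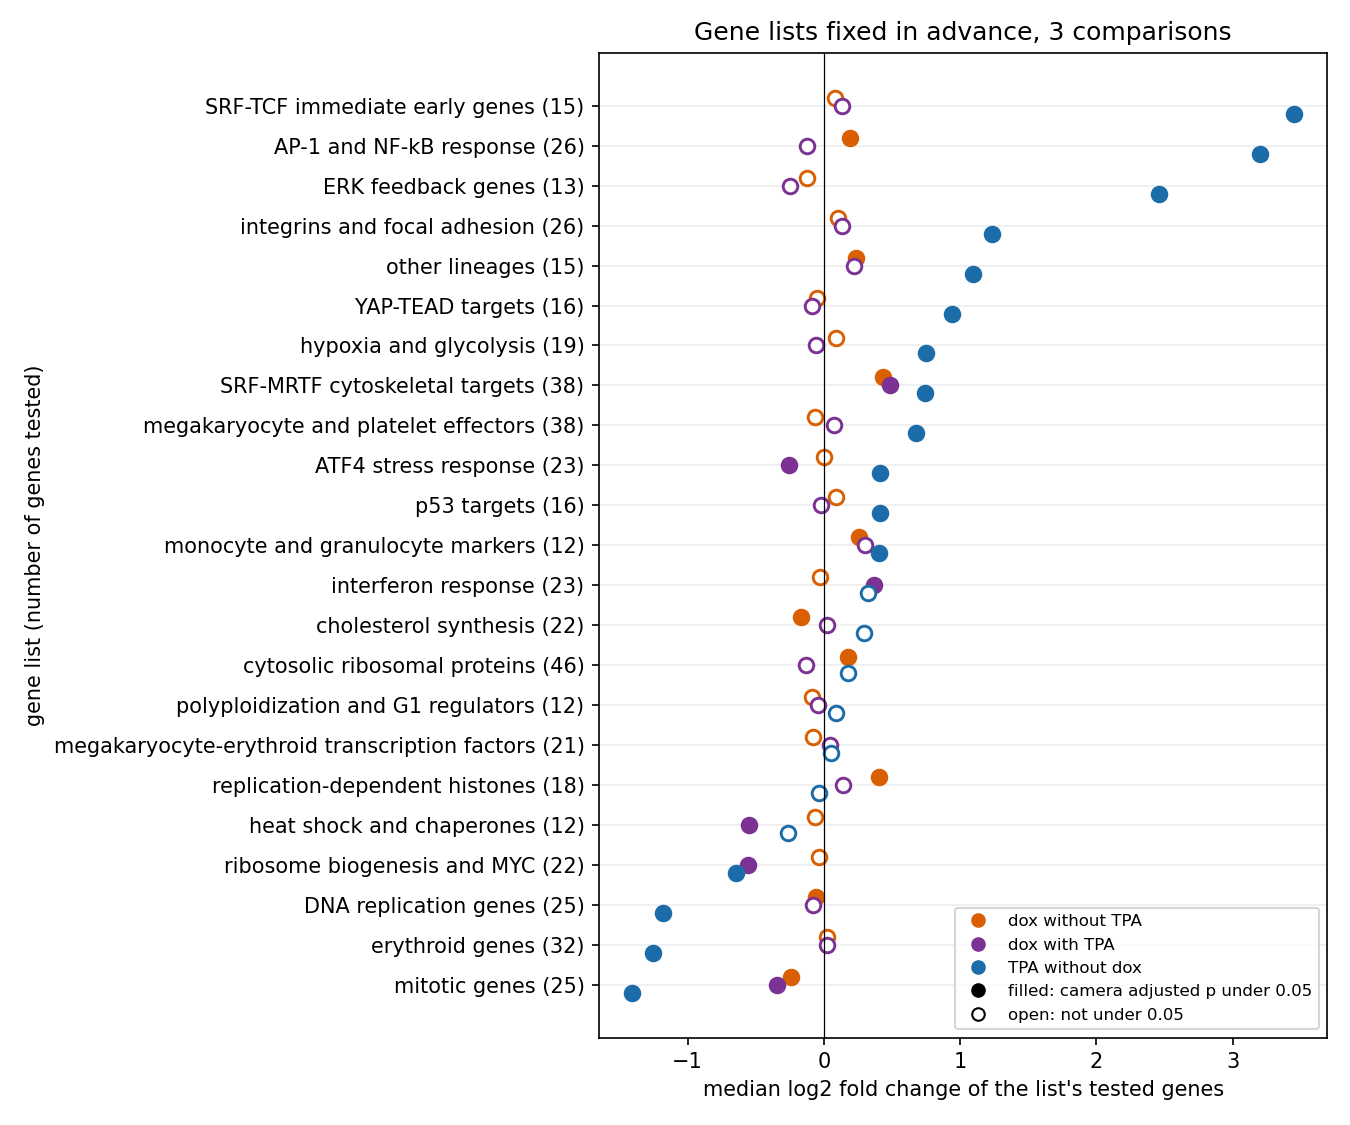
Median log2 fold change of the tested members of each of 23 gene lists for dox without TPA, dox with TPA and TPA without dox; filled points passed 0.05 by camera with a preset correlation. The TPA medians run from -1.41 (mitotic genes) to 3.45 (immediate early genes), and the dox medians without TPA from -0.24 to 0.44.

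With both treatments together, most SRF and MRTF targets and 22 of 38 megakaryocyte and platelet effectors stood above untreated cells. ACTG2 was 503-fold above untreated (8.97 ± 0.17, n = 2), ITGA2B 2.92-fold (1.55 ± 0.12), MYH9 2.90-fold (1.54 ± 0.14), VWF, the von Willebrand factor, 6.29-fold (2.65 ± 0.16) and SRF 1.70-fold (0.77 ± 0.13), with edgeR QL adjusted p from 2.9e-13 to 0.000195. Of the 38 SRF and MRTF targets 34 were higher, 1 lower (TPM1) and 3 not past, with a median of 1.48 (camera adjusted p = 2.45e-10, and 0.101 with an estimated correlation). Of the effectors 22 were higher, 2 lower, F13A1 (-3.13 ± 0.45) and PPBP (-1.02 ± 0.13), and 14 not past, GP1BA among them (edgeR QL adjusted p = 0.141), also adjusted over the list alone. Their median was 0.65 (camera adjusted p = 0.000336, and 0.107 with an estimated correlation). The TPM1 call was lost without untreated replicate 2 (edgeR QL adjusted p = 0.0717). In all 8478 genes passed, 4378 higher and 4100 lower, and library size alone moved the median of all genes by -0.10. By camera 16 of 23 lists passed, and 4 with an estimated correlation. Without dox+TPA replicate 2 the p53 list was lost (camera adjusted p = 0.0593) and ribosomal proteins passed (0.0472), and cholesterol synthesis passed without untreated replicate 2 (0.0273). With a GC content trend removed the monocyte and p53 lists were lost (camera adjusted p = 0.0715 for both) and cholesterol synthesis passed (0.0489), and interferon genes passed with library size alone (0.0483). By fry 21 lists passed.

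TPA in dox-treated cells moved much the same genes as TPA in untreated cells. ITGA2B rose 2.89-fold (1.53 ± 0.12), ITGB3 3.94-fold (1.98 ± 0.11) and CDKN1A 5.24-fold (2.39 ± 0.10), with edgeR QL adjusted p from 3.34e-10 to 1.74e-07. GP1BA was 1.32-fold higher (0.40 ± 0.12, edgeR QL adjusted p = 0.0148), a call lost without dox replicate 1 (0.0655), dox replicate 2 (0.0903) or dox+TPA replicate 2 (0.0727). In all 8070 genes passed, 4082 higher and 3988 lower, and by camera 17 of 23 lists, or 4 with an estimated correlation and 21 by fry. Monocyte markers were lost without dox replicate 2 (camera adjusted p = 0.0761), either TPA library (0.0542 and 0.0548) or dox+TPA replicate 2 (0.0608), or with a GC content trend removed (0.11), and ribosomal proteins and histones passed without dox+TPA replicate 1 (0.00107 and 0.0483), the former also with library size alone (0.0265). Of the genes past in the 2 TPA contrasts 3141 were higher in both, against 1120 for independent sets, 2803 lower in both, against 983, and 42 opposite, with r = 0.888 across genes.

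Whether dox moved genes the way TPA did was also asked, in contrasts that share the untreated libraries. Of the 125 genes higher with dox 71 were higher with TPA, against 34.3 for independent sets, 5 of the 21 lower genes were lower with TPA, against 5.18, and 28 went opposite ways. Part of the 71 may come from the shared controls. In 100 simulated count sets with no effect in any gene, 0.33 genes passed in the same direction on average and at most 3, which sets no bound for the 76 found where many genes respond to TPA. The correlation across genes was r = 0.215, against 0.496 in the simulated sets, and the share of genes with the same sign was 57.4% against 66.7%. The simulated sets held no TPA response, while 7533 genes passed with TPA in the data, which changes both measures. Neither therefore shows whether dox moved genes more or less like TPA than shared controls alone would give. The covariance, 0.106, exceeded the simulated 0.0433. The 76 became 29 without untreated replicate 1, 42 without untreated replicate 2, 37 without dox replicate 1, 204 without dox+TPA replicate 1 and 203 without dox+TPA replicate 2.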

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

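The tests of gene length and GC content on the ribosomal protein genes, of single libraries on the counts, and of the SRF and MRTF targets were chosen only after the results were seen.

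A difference between groups, the dox effect with TPA against that without, was tested as an interaction, and 290 genes passed it by edgeR QL. The largest positive values on the log2 scale were C1orf95 at 2.841, TAGLN at 2.80, WWC1 at 2.191, CHD5 at 2.076, RHOB at 2.027, COL25A1 at 1.639, CALD1 at 1.638 and DUSP5P at 1.591. The largest negative values were GFPT2 at -4.144, S100A2 at -3.028, FASLG at -2.142, GLIPR1 at -1.895 (turned to 0.40 from RPKM with pseudocount 1), PRR9 at -1.629, S100A6 at -1.625 and STC1 at -1.61. Among lists the camera adjusted p was 2.57e-09 for ribosome biogenesis and MYC, 1.9e-05 for ribosomal proteins, 0.000249 for heat shock, 0.00161 for AP-1 and NF-kB, 0.00415 for interferon, 0.00431 for cholesterol and 0.0148 for megakaryocyte effector genes, none of which passed with an estimated correlation (0.139 to 0.591).

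More genes passed for dox with TPA (3329) than without (146), a ratio of 22.8, but with each fitted on just its own 2 groups the counts were 1404 and 901, a ratio of 1.56, so its size depended on the libraries in the fit. In the fit of all 4 groups the lowest ratio with any library left out was 6.15, without dox+TPA replicate 1. More genes thus passed with TPA in that fit whichever library was left out, although the size of the ratio depended strongly on single libraries. No library was left out in the fits of just 2 groups, so whether 1 library carries the ratio of 1.56 cannot be told. Standard errors were not smaller with TPA. Their median was 0.123 with TPA and 0.12 without in the fit of all 4 groups. With just the 2 groups fitted it was larger with TPA (0.144 against 0.0988). The spread of fold changes beyond their standard errors was 2.27 times larger with TPA (0.245 against 0.108 over 9236 genes), and 1.85 times with just the 2 groups fitted. That spread concerns the size of effects. Standard errors taken from the replicates of the compared groups were 0.103 without TPA and 0.167 with it. The spread beyond them was 1.76 times larger with TPA. The shared fit thus set the noise too high without TPA and too low with it, against these values. Most of the ratio of 22.8 therefore depended on the shared fit. The exact share stays open, since the fits of 2 groups also hold fewer libraries and filter genes anew. A stronger response of the SRF and MRTF targets stays open, since their median interaction was -0.048 over members that went both ways, 18 of 38 above 0. MKL1 itself was higher with both treatments, and a broader response to more MKL1 in cells also given TPA may be part of the difference, which was not tested.

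Ribosomal protein genes stood slightly higher with dox alone, with a median of 0.176 over 46 genes (camera adjusted p = 4.05e-07, but 0.453 with an estimated correlation, and fry adjusted p = 0.255). Removing a gene length trend between libraries left a median of 0.044 (camera adjusted p = 0.0665), so such a trend stays possible as a cause. The trend was drawn from all well expressed genes, ribosomal protein genes included. A real change shared by genes of similar length would be removed with it, so this test cannot tell them apart. Removing a GC content trend left 0.145 (camera adjusted p = 1.46e-05), which argues against that trend as the whole cause of the median. No biological explanation was tested, and these genes have many pseudogenes that can share reads.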

How the results depend on the processing

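The crossed replicate block and the removal of gene length and GC content trends were chosen only after the results were seen.

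For dox without TPA, 146 genes became 376 with no filter, 901 with just the 2 groups compared, 929 with the crossed block, 527 with the GC trend removed, 78 at a fold of 2, 79 at an adjusted p under 0.01, and 61, 69 and 47 from RPKM at pseudocount 1, at 0.1 and unfiltered. Leaving out a library gave 57 to 399. For dox with TPA, 3329 became 1404 with just the 2 groups, 6023 with the crossed block, 622 at a fold of 2, 1362 under 0.01 and 2123 from unfiltered RPKM, and 1025 to 4529 without a library. For the interaction, 290 became 518 with DESeq2, 965 with no filter, 536 with the replicate block, 2500 with the crossed block, 2159 with the GC trend removed, 125 at a fold of 2, 23 under 0.01, 171, 75 and 92 from RPKM, and 16 to 895 without a library. TPA gave 2847 at a fold of 2 without dox (6111 to 8317 without a library) and 3056 with it (6416 to 8082), and both treatments 3420 (7213 to 8523). Genes shared by the 2 dox effects were 66 under 0.01 (53 to 249 without a library), and those shared by dox and TPA 42 (29 to 204). A fold of 2 and an adjusted p of 0.01 lower counts by construction. For the other settings the cause was not tested. The counts for dox without TPA and for the interaction grew without either dox+TPA library. The dox+TPA pair, which had the largest SD between replicates (0.277), then no longer enters the shared estimate of noise. How far this accounts for the growth, or for that of other counts, was not tested.

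The MKL1 rise with dox ranged from 2.724 to 3.058 with a library left out, and from 3.367 to 3.69 in TPA-treated cells. The GLIPR1 interaction reversed to 0.40 from RPKM at pseudocount 1, filtered or not, but not at 0.1, so its sign depended on the pseudocount. JUND, dox with TPA, reversed to -0.099 with the GC content trend removed, and the interferon list under TPA to an adjusted p of 0.0395 downwards by fry. The cause of the JUND and interferon reversals was not tested. Of the named genes' calls, 351 were lost and 14 gained over all omissions of a library against 3240 the same, 26 lost and 4 gained with DESeq2 against 415, and 9 lost and 1 gained with RLE against 441. With an estimated correlation 61 list calls were lost and 77 list outcomes were the same. Outcomes counted as the same, for genes and lists, include those past in neither setting. The list calls kept were 2 for TPA without dox, 4 for TPA with dox and 4 for both treatments together. Whether replicate numbers pair the libraries is not stated in the labels. Same-numbered libraries deviated together among the treated groups (correlations of 0.152 to 0.348) but not against the untreated group (-0.128 to -0.0609). The fit without a replicate block was kept. A block by replicate number moved just the interaction count by over 1.5 times. The crossed block, with the untreated numbers exchanged, gave 929 genes for dox without TPA, 6023 for dox with TPA and 2500 for the interaction. A factor shared by libraries of different groups may thus remain in the noise of the main fit. The labels do not settle this. Dox+TPA replicate 1 holds 12238348 reads, which limits calls for weakly expressed genes in that group.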

Other observations

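The list of endoplasmic reticulum chaperone genes, the tests without dox+TPA replicate 1 and of dox itself, and the removal of gene length and GC content trends were chosen only after the result was seen.

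Genes of protein folding in the endoplasmic reticulum rose with TPA and fell when dox was added to it. HSPA5 had 1030 ± 119 CPM untreated, 832 ± 75.2 with dox, 1640 ± 75.9 with TPA and 506 ± 1.22 with both (mean ± SD, n = 2), and DNAJB9, a cochaperone, 25.9 ± 2.12 untreated, 76.7 ± 8.48 with TPA and 28.2 ± 1.07 with both. HSP90B1, the chaperone GRP94, fell with dox under TPA by 1.01 on the log2 scale (edgeR QL adjusted p = 3.8e-05), and PDIA4, a disulfide isomerase, by 0.88 (edgeR QL adjusted p = 0.000145). Over 20 such genes, chosen after their values were seen, 18 were higher and 2 not past with TPA alone (median 0.699), and 18 were lower and 2 not past with dox under TPA (median -0.837). The interaction had a median of -0.672, with 8 lower and 12 not past. Against untreated cells, both treatments together left 2 higher, 5 lower and 13 not past (median -0.0916).

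This pattern was found and tested on the same data and is a hypothesis. The rise with TPA and the fall with dox under TPA share the TPA libraries, so a deviation of those libraries would appear in both. The shallow dox+TPA replicate 1 does not account for it, since the median without that library was -0.913. Removing a gene length trend left -0.757 and removing a GC content trend -0.817, which argues against either trend as the whole cause. Doxycycline itself stays open: dox without TPA gave a median of -0.166, and the series holds no dox-treated line without the transgene. A lower load of secreted proteins with MKL1 in TPA-treated cells may be a further explanation, and it was not tested.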
